A study of Mus musculus with 18 samples.

How the data were processed

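RNA was measured in 18 libraries of mouse cells, 3 per group of genotype (WT or orpk) and shear (static, 2 or 30 dyn/cm²), with groups taken from the labels. Libraries were stranded poly(A) libraries read as single 50-nt ends, per the labels. Per the labels, reads were processed with CASAVA 1.8.2, aligned to GRCm38 with STAR 2.4 and counted per gene with featureCounts 1.4.6, as the submitters' processing notes give it. The values deposited are the read count per gene and library, as whole numbers. The notes do not say whether counting used the strand or how reads with several matches were treated. Genes with close copies elsewhere in the genome, such as ribosomal protein genes, Gapdh and Ftl1, therefore have less certain levels. Of 69 named genes with a location, 32 overlap another annotated gene and 28 one on the other strand, Ift88 among them, so their reads could include those of the neighbour. Locations are those of GENCODE M21 on GRCm38, the build the notes name.

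The table lists 21647 genes, 3937 of them without reads, and 21583 have a symbol in GENCODE M21. Genes absent from the table, such as Xist, and genes below the filter, such as Thbd, are not analysed here. Library totals ran from 13626480 to 17387553 counts, a ratio of 1.28, and intervals and floors cover counting error alone. With R 4.3.3 and edgeR 4.0.16, genes were kept by filterByExpr at its defaults (13058 genes), scaled by TMM, and fitted with a robust quasi-likelihood model of 6 group means. The biological coefficient of variation was 3.28% with 12 residual degrees of freedom. Contrasts were tested by edgeR's quasi-likelihood F test with Benjamini-Hochberg (BH) adjustment at 0.05 within each of 12 comparisons. These were 3 shear comparisons in each genotype, 3 of genotype at each shear, and 3 interactions. CPM are TMM-normalised, SD are over the 3 libraries of a group, and SE of a log2 fold change is its size over the root of F. The p-values measure the spread between these libraries, which may be technical, since the labels name no separate animals or isolations. A gene at 0 reads in a group is given as a bound against a floor of 3 reads over the group, and at 1 to 3 reads as a ratio with a 95% exact counting interval.

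The tests, the 31 gene lists and the naming rule were fixed before the data were examined. Lists with at least 5 tested genes (29 of 31) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and BH was applied over the lists of a comparison. The lymphatic list had 1 tested gene and the mitochondrial list 0, so neither was tested. Named by rule were 9 genes in every comparison (Ift88, Klf2, Klf4, Nos3, Thbd, Edn1, Vcam1, Acta2 and Pecam1). To these came, among genes past the threshold with a mean of at least 5 CPM, a regular symbol and no overlap between the libraries of the groups, the 8 highest and 8 lowest log2 fold changes. In the comparisons of 30 with 2 dyn/cm² and in interactions these were 5 and 5, of which interaction genes with 3 or fewer reads in a group are left out. Of each list, up to 4 members past the threshold with the largest change could be named. The text gives a selection of these genes, chosen after their values were seen, as were Cd34, Cdh5, Mcam, Ets1, Flt1, Krt19, Msln and the kidney genes. With 3 libraries against 3, chance gives no overlap for 10% of genes.

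The method was tested on simulated data, with 200 genes changed, 50 per size, among counts drawn with the fitted dispersions. Their means were 1 level per genotype without an effect of flow, or the WT level in every library for the genotype comparisons. The changed genes were drawn from those with a mean of at least 1 CPM, over the WT libraries for the genotype comparisons and over all libraries otherwise. Genes with a lower mean were not changed, so the share found among them is not known. In the order of 6 shear comparisons, 3 interactions and 3 genotype comparisons, a log2 change of 1 was found in 84, 82, 94, 100, 90, 94, 86, 84, 86, 100, 100, 98% of genes. A change of 0.5 was found in 78, 84, 84, 84, 80, 84, 64, 78, 68, 86, 94, 92%, one of 0.25 in 50, 62, 64, 64, 44, 40, 28, 24, 20, 56, 50, 58% and one of 0.1 in 4, 4, 2, 0, 2, 4, 0, 2, 0, 2, 2, 6%. False calls made up 1.69% to 7.69% of calls. As many more genes passed in the real comparisons, these shares need not hold there. Alternatives were RLE factors, library totals as the scaling, no filter, DESeq2 1.42.0, the compared groups alone, each library left out in turn, replicate number as a block, other list tests, other Ift88 scalings and, chosen after seeing the data, the list tests without WT replicate 1 or orpk replicate 2 at 2 dyn/cm².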

Results

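The series measured poly(A) RNA in cultured mouse embryonic aortic endothelial cells, as the labels name them, under laminar flow. Cells were wild type (WT) or homozygous for orpk, an insertion in Ift88, a gene whose protein carries cargo along the primary cilium. Each genotype was kept static, or was sheared at 2 or 30 dyn/cm² for 48 h, after 24 h of serum starvation. The 48 h is the time of flow, and the time for which static cells were kept is not given here. Each of the 6 groups held 3 libraries, 18 in total, and the library totals ran from 13626480 to 17387553 counts. In all, 13058 of 21647 listed genes had enough reads to test. The first principal component took 90.1% of the variance and separated the genotypes, and the second took 4.38% and followed flow.

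**Figure D1:**
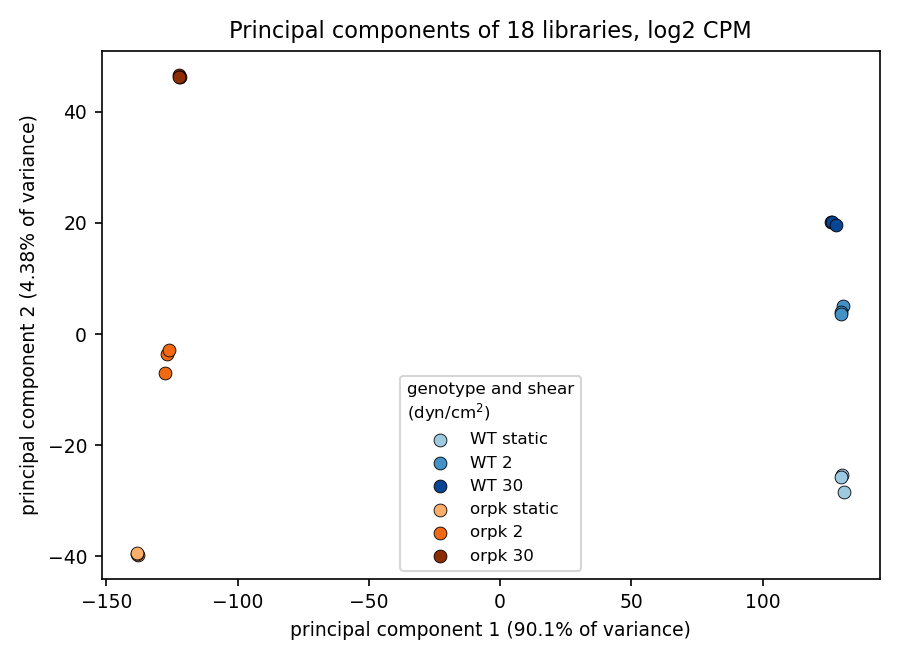
Principal components 1 and 2 of log2 CPM for the 18 libraries, 1 point per library, coloured by genotype and shear in dyn/cm². Component 1 holds 90.1% of the variance and parts WT from orpk.

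Ift88 (ENSMUSG00000040040, GRCm38 chromosome 14, 57424062 to 57517936, plus strand) was still transcribed in orpk cells, 1.99-fold below the WT level in static culture. The static WT libraries held 13.4, 17.4 and 15.98 CPM, and the static orpk libraries held 7.49, 8.46 and 7.47 CPM. At 2 dyn/cm² the WT libraries held 13.9, 15.5 and 14.2 CPM and the orpk libraries 7.87, 7.16 and 8.17 CPM. At 30 dyn/cm² these were 12.8, 13.3 and 13.9 CPM in WT and 6.37, 7.36 and 6.98 CPM in orpk. The log2 fold change of orpk against WT was -0.99 ± 0.10 (SE) in static cells, -0.91 ± 0.10 at 2 and -0.95 ± 0.11 at 30 dyn/cm². The libraries of the genotypes did not overlap at any shear (edgeR quasi-likelihood adjusted p = 5.61e-12, 3.11e-11 and 8.68e-11). Among the 11465 genes past the threshold between the genotypes in static cells, the median absolute log2 fold change was 0.89. The Ift88 difference is thus of a size common in this comparison, and its size alone does not tie it to the mutation. In WT, Ift88 fell by 0.22 on the log2 scale from static to 30 dyn/cm² (SE 0.09, edgeR adjusted p = 0.0213). That call was lost with library totals as the scaling and when any of 4 of the 6 libraries was left out. In orpk the change from static to 30 dyn/cm² was -0.18 ± 0.12 and did not pass (edgeR adjusted p = 0.189), and the difference between those changes was 0.04 ± 0.15 (edgeR adjusted p = 0.843). Gene counts do not show where along the transcript the remaining reads lie, so they cannot show whether the remaining transcript is intact.

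The first question is how WT cells respond to low shear, 2 dyn/cm² against static. Genes of glycolysis and of the hypoxia response, which cells raise when oxygen is short, fell together. Bnip3, a mitochondrial hypoxia-response protein, fell 20.2-fold, from 205 ± 10.6 to 10.1 ± 1.69 CPM (log2 fold change -4.34 ± 0.07 SE), with n = 3 in each group here and in every comparison. Pdk1, a mitochondrial kinase that inhibits pyruvate dehydrogenase, fell 10.7-fold, from 338 ± 10.8 to 31.5 ± 1.07 CPM (log2 fold change -3.42 ± 0.05 SE). Of 16 tested hypoxia genes 15 fell and 0 rose, with a median log2 fold change of -2.52 (camera adjusted p = 4.45e-81). Of 21 glycolysis genes 20 fell and 0 rose, median -2.18 (camera adjusted p = 2.60e-118). Sterol synthesis genes also fell, 22 of 24 with 1 higher and a median of -0.80 (camera adjusted p = 2.22e-32), led by Lss (-1.80 ± 0.04) and Hmgcs1 (-1.28 ± 0.04). Targets of the p53 tumour suppressor rose, 15 of 16 with 0 lower, median 0.54 (camera adjusted p = 5.60e-09), including Eda2r (2.56 ± 0.13) and Ccng1 (1.92 ± 0.04). Epithelial and mesothelial markers were lower in 4 of 9 and higher in 1, median -0.22 (camera adjusted p = 0.0119). These 5 calls held with an estimated correlation, and their counts were the same when adjusted over the list alone. In WT at 2 dyn/cm² replicate 1 stood apart, with a chi-square per degree of freedom of 6.35 and 7.74 against the others and 1.44 between those. Without it the epithelial call was lost with an estimated correlation (adjusted p = 0.0616, median -0.21, 5 lower), and the other 4 held.

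Angptl4, which encodes an inhibitor of lipoprotein lipase, rose 37.3-fold, from 1.61 ± 0.212 to 60.5 ± 4.07 CPM (log2 fold change 5.22 ± 0.11 SE), the highest rise under the naming rule. It was followed by Fbp2 (3.48 ± 0.14) and Inka2 (3.33 ± 0.14), and Cyp1b1, a xenobiotic oxidase, rose 5.05-fold, from 25.9 ± 1.95 to 131 ± 3.08 CPM (log2 fold change 2.34 ± 0.05 SE). Car9, a carbonic anhydrase raised by low oxygen, fell 29.3-fold, from 13.4 ± 0.805 to 0.456 ± 0.195 CPM (log2 fold change -4.87 ± 0.19 SE). Aire had 666 reads over the static libraries and 0 under flow, so it was at least 253-fold lower against a floor of 3 reads over the group. Among genes known to respond to shear in endothelium, Klf4 fell (log2 fold change -1.45 ± 0.08), as did Edn1 (-1.10 ± 0.14), Vcam1 (-1.72 ± 0.19) and Nos3 (-0.96 ± 0.23). Klf2 did not pass (0.17 ± 0.14, edgeR adjusted p = 0.301). The whole laminar shear list had 4 of 20 genes higher and 10 lower, median -0.32 and a camera direction of up (adjusted p = 0.943), which is opposite in sign to its median and mean. Of 22 NRF2 antioxidant genes 18 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 4.08e-06; adjusted p = 0.14 with an estimated correlation). In all, 8214 of 13058 tested genes passed the threshold, 4254 higher and 3960 lower (5630 higher and 2916 lower with library totals as the scaling), and 317 higher and 524 lower changed by over 1 on the log2 scale.

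At 30 dyn/cm² against static, the question is what high laminar shear does to WT cells. The hypoxia, glycolysis and sterol genes were lower than in static cells, with medians of -2.56, -2.22 and -0.94. In turn 15 of 16, 20 of 21 and 22 of 24 genes were lower (camera adjusted p = 5.78e-65, 3.77e-89 and 3.08e-30). Ccn2, a matricellular target of the YAP and TAZ coactivators, rose 6.24-fold, from 50.6 ± 6.296 to 316 ± 6.75 CPM (log2 fold change 2.64 ± 0.09 SE). The YAP and TAZ target list as a whole was not among the 5 lists that passed camera in this comparison. Angptl4 rose 60.3-fold, from 1.61 ± 0.212 to 97.9 ± 5.08 CPM (log2 fold change 5.91 ± 0.10 SE). Ctsw, a cathepsin protease, rose 20.7-fold, from 0.573 ± 0.273 to 12.1 ± 0.0901 CPM (log2 fold change 4.38 ± 0.19 SE). Immediate early genes, transcribed first after a stimulus, were higher in 13 of 17 and lower in 1, and in 13 and 3 when adjusted over the list alone (median 0.71, camera adjusted p = 0.00348). They included Fosb (1.58 ± 0.19), Egr2 (1.57 ± 0.19) and Egr3 (1.30 ± 0.23). Targets of p53 were higher in 12 of 16 and lower in 1 (median 0.62, camera adjusted p = 5.77e-06). Except for immediate early genes, these list counts were the same when adjusted over the list alone, and all 5 calls held with an estimated correlation. Vcam1, a leukocyte adhesion molecule, fell 7.36-fold, from 10.2 ± 0.535 to 1.37 ± 0.327 CPM (log2 fold change -2.88 ± 0.23 SE). Klf4 and Edn1 fell by 1.26 and 0.83 on the log2 scale, and neither Klf2 (0.05 ± 0.15) nor Nos3 (-0.46 ± 0.21) passed (edgeR adjusted p = 0.799 and 0.0546). In all, 8731 of 13058 tested genes passed the threshold, 4455 higher and 4276 lower (5389 higher and 3485 lower with library totals as the scaling), with 467 higher and 802 lower by over 1 on the log2 scale.

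Between 2 and 30 dyn/cm² in WT, the question is what the size of the shear adds. Ccn2 rose 3.27-fold, from 96.7 ± 1.08 to 316 ± 6.75 CPM (log2 fold change 1.71 ± 0.08 SE). Ctsw and the cardiac troponin gene Tnnt2 had log2 fold changes of 4.32 ± 0.18 and 2.92 ± 0.11. Ifit3, an interferon-induced gene, fell 12.5-fold, from 9.997 ± 1.69 to 0.796 ± 0.168 CPM (log2 fold change -3.64 ± 0.19 SE). Mesenchymal and contractile genes were higher in 9 of 22 and lower in 2, and higher in 10 when adjusted over the list alone (median 0.13, camera adjusted p = 0.00139; adjusted p = 0.10 with an estimated correlation). Among the contractile genes, calponin (Cnn1) fell (-1.55 ± 0.22). Smooth muscle and pericyte markers were higher in 3 of 5 and lower in 0 (median 0.41, camera adjusted p = 0.0379; adjusted p = 0.10 with an estimated correlation). Macrophage and leukocyte markers were lower in 1 of 7 and higher in 0 (median -0.29, camera adjusted p = 0.00907; adjusted p = 0.0867 with an estimated correlation), and both counts were the same adjusted over the list alone. Matrix genes were higher in 11 of 37 and lower in 5, or 12 and 6 when adjusted over the list alone (median 0.02, camera adjusted p = 0.00162; adjusted p = 0.46 with an estimated correlation). Without replicate 1 at 2 dyn/cm², which stood apart, matrix genes were 9 higher and 8 lower (median 0.14, camera adjusted p = 0.00443; adjusted p = 0.58003 with an estimated correlation). Sterol genes were lower in 14 of 24 and higher in 1, the same adjusted over the list alone (median -0.14, camera adjusted p = 0.00907; adjusted p = 0.21 with an estimated correlation), with Hmgcs1 at -0.27 ± 0.04. Interferon genes, of an antiviral program, were lower in 19 of 26 and higher in 0, and lower in 22 when adjusted over the list alone (median -1.02, or -0.96 with genes at 0 reads set to their bound, camera adjusted p = 9.69e-11; adjusted p = 0.10 with an estimated correlation). Of the 29 lists tested here, 11 passed camera and 18 passed fry. With an estimated correlation 0 of the 29 passed, and 8 had an unadjusted p under 0.05. Klf2, Klf4, Nos3 and Edn1 did not pass, and Vcam1 fell (-1.15 ± 0.30), a call lost without replicate 1 at 2 dyn/cm² (-1.19). The hypoxia list had 6 genes lower and 1 higher of 16 (median -0.07, mean 0.03, camera direction down, opposite to the mean, adjusted p = 0.0698), the same adjusted over the list alone. In it Bnip3 (-0.54 ± 0.11) and Pdk1 (-0.64 ± 0.07) fell. In all, 4316 of 13058 tested genes passed the threshold, 2071 higher and 2245 lower (1698 higher and 2643 lower with library totals as the scaling), with 133 higher and 181 lower by over 1 on the log2 scale.

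The same question was asked of orpk cells, which carry the Ift88 mutation, at 2 dyn/cm² against static. Replication genes rose, 24 of 24 with 0 lower and a median of 1.31 (camera adjusted p = 2.78e-64). Rrm2, which makes deoxynucleotides for DNA synthesis, rose 4.502-fold, from 53.2 ± 1.11 to 239.5 ± 11.6 CPM (log2 fold change 2.17 ± 0.04 SE), and Ccne2 (1.98 ± 0.06) and Cdc6 (1.98 ± 0.06) rose with it. Hypoxia and glycolysis genes fell in 15 of 16 and 20 of 21, with 0 and 0 higher and medians of -1.76 and -1.24 (camera adjusted p = 1.13e-59 and 1.66e-55). Adm, the vasodilator peptide adrenomedullin, fell 49.3-fold, from 36.4 ± 1.84 to 0.724 ± 0.314 CPM (log2 fold change -5.62 ± 0.14 SE). Sterol synthesis genes rose in 22 of 24 and fell in 1, median 0.44 (camera adjusted p = 8.10e-08), including Hsd17b7 (1.09 ± 0.05) and Tm7sf2 (0.93 ± 0.08). These 4 calls held with an estimated correlation, and their counts were the same when adjusted over the list alone. Angptl4 rose 76.9-fold, from 0.2801 ± 0.149 to 22.005 ± 2.09 CPM (log2 fold change 6.26 ± 0.20 SE). Klf2 fell 3.64-fold, from 28.1 ± 2.496 to 7.67 ± 1.78 CPM (log2 fold change -1.86 ± 0.11 SE) and Klf4 had a log2 fold change of -0.57 ± 0.05. Acta2, smooth muscle actin, rose 1.68-fold, from 659 ± 40.9 to 1104 ± 93.6 CPM (log2 fold change 0.74 ± 0.05 SE). Neither Edn1 (0.02 ± 0.15) nor Vcam1 (0.13 ± 0.06) passed (edgeR adjusted p = 0.918 and 0.0909). Matrix genes were lower in 25 of 37 and higher in 7, the same when adjusted over the list alone (median -0.37, camera adjusted p = 5.72e-04; adjusted p = 0.40 with an estimated correlation). Fibroblast markers were lower in 7 of 10 and higher in 1, or 2 adjusted over the list alone (median -0.51, camera adjusted p = 7.17e-04; adjusted p = 0.19 with an estimated correlation). Smooth muscle and pericyte markers were higher in 3 of 5 and lower in 1, the same adjusted over the list alone (median 0.76, camera adjusted p = 0.0417; adjusted p = 0.16 with an estimated correlation). In orpk at 2 dyn/cm² replicate 2 stood apart, with a chi-square per degree of freedom of 3.39 and 3.79 against the others and 1.58 between those. Without it matrix genes were 28 lower and 5 higher (median -0.50, camera adjusted p = 8.02e-07; adjusted p = 0.0692 with an estimated correlation). Without it the smooth muscle call was lost (camera adjusted p = 0.1101), and the replication, hypoxia, glycolysis and sterol calls held with an estimated correlation. In all, 8090 of 13058 tested genes passed the threshold, 4030 higher and 4060 lower (5372 higher and 2982 lower with library totals as the scaling), with 429 higher and 556 lower by over 1 on the log2 scale.

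At 30 dyn/cm² against static, orpk cells changed most among the flow comparisons, by count of genes. Ccn2 rose 42.1-fold, from 10.3 ± 2.304 to 439 ± 9.79 CPM (log2 fold change 5.40 ± 0.11 SE), with Ccn1 (2.55 ± 0.04) and Tead4 (2.24 ± 0.09). Of 23 YAP and TAZ targets 15 rose and 5 fell (median 0.37, camera adjusted p = 1.10e-05). Sterol synthesis genes rose in 24 of 24, median 1.23 (camera adjusted p = 6.42e-36), and Tm7sf2, a sterol reductase, rose 5.73-fold, from 17.1 ± 1.84 to 98.2 ± 1.36 CPM (log2 fold change 2.52 ± 0.07 SE). Hypoxia genes fell in 15 of 16, median -2.32, and glycolysis genes in 19 of 21, median -1.84, with 1 higher (camera adjusted p = 1.92e-37 and 3.11e-50). These 4 calls held with an estimated correlation, and adjusted over the list alone the counts differed only for glycolysis, with 20 lower. Adm fell 275-fold, from 36.4 ± 1.84 to 0.125 ± 0.0868 CPM (log2 fold change -8.10 ± 0.21 SE). Apln, the peptide apelin, fell 43.1-fold, from 134 ± 2.52 to 3.11 ± 0.397 CPM (log2 fold change -5.43 ± 0.09 SE). Agtr2, an angiotensin receptor, had 2 reads at 30 dyn/cm² against 635 in static cells, a ratio of 256 with a 95% counting interval of 81.6 to 2449.8.

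Of 37 matrix genes in orpk at 30 dyn/cm², 15 were higher and 16 lower, with a median of -0.14, a mean of -0.14 and a camera direction of up (adjusted p = 0.243). Of 22 mesenchymal and contractile genes 11 were higher and 8 lower (median 0.17, camera adjusted p = 0.115), and both counts were the same adjusted over the list alone. Fibroblast markers were lower in 6 of 10 and higher in 3, the same adjusted over the list alone (median -0.21, camera adjusted p = 0.00162; adjusted p = 0.22 with an estimated correlation). Acta2 and Tagln rose (1.61 ± 0.05 and 2.07 ± 0.06), and the fibroblast receptor gene Pdgfra fell 11.9-fold, from 1775 ± 18.2 to 149 ± 4.97 CPM (log2 fold change -3.58 ± 0.05 SE). Klf4 rose 1.93-fold, from 133 ± 5.88 to 257 ± 5.602 CPM (log2 fold change 0.94 ± 0.05 SE) and Edn1 rose (1.18 ± 0.13), while Klf2 (-0.81 ± 0.10) and Vcam1 (-1.15 ± 0.07) fell. Interferon genes were lower in 24 of 26 and higher in 0, the same when adjusted over the list alone (median -1.88, camera adjusted p = 1.99e-07; adjusted p = 0.19 with an estimated correlation). Replication genes were higher in 24 of 24 (median 0.84, camera adjusted p = 2.17e-12; adjusted p = 0.13 with an estimated correlation). The G2/M genes of mitosis were lower in 18 of 24 and higher in 4 (median -0.52, camera adjusted p = 6.92e-04; adjusted p = 0.43 with an estimated correlation). Both counts were the same adjusted over the list alone. The smooth muscle and pericyte list went both ways, with 2 of 5 higher and 3 lower, the same adjusted over the list alone. It had a median of -0.35, a mean of 0.41 and a camera direction of up (adjusted p = 0.0409; adjusted p = 0.13 with an estimated correlation). In all, 9123 of 13058 tested genes passed the threshold, 4769 higher and 4354 lower, with 648 higher and 1220 lower by over 1 on the log2 scale.

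From 2 to 30 dyn/cm² in orpk cells, sterol synthesis genes rose. G2/M genes fell and unfolded protein and amino acid stress genes rose, 2 calls that were lost with an estimated correlation. Mki67, the marker of cycling cells, fell 2.399-fold, from 472 ± 13.2 to 197 ± 12.9 CPM (log2 fold change -1.26 ± 0.06 SE). Of 24 G2/M genes 24 fell, with 0 higher (median -0.88, camera adjusted p = 3.17e-22; adjusted p = 0.0565 with an estimated correlation). Sterol synthesis genes rose in 24 of 24 (median 0.89, camera adjusted p = 2.38e-27). Unfolded protein and amino acid stress genes rose in 18 of 19 (median 0.46, camera adjusted p = 1.23e-10, and 0.0565 with an estimated correlation). They were led by Trib3 (2.12 ± 0.06), Chac1 (1.8 ± 0.07) and Asns (1.59 ± 0.04). Genes of the TGF-beta and BMP response were higher in 12 of 28 and lower in 8 (median 0.26, camera adjusted p = 4.95e-04), and this and the sterol call held with an estimated correlation. The counts of these 4 lists were the same when adjusted over the list alone. Without replicate 2 at 2 dyn/cm², which stood apart, the G2/M and stress calls also held with an estimated correlation (camera adjusted p = 0.0458 and 0.0349). Anxa8, an annexin, rose 18.9-fold, from 17.2 ± 1.77 to 326 ± 6.01 CPM (log2 fold change 4.24 ± 0.06 SE). Txnip, a brake on glucose uptake, fell 18.5-fold, from 344 ± 48.7 to 18.7 ± 1.38 CPM (log2 fold change -4.21 ± 0.11 SE). Klf2, Klf4, Edn1 and Acta2 rose (1.05 ± 0.12, 1.51 ± 0.05, 1.16 ± 0.13 and 0.86 ± 0.05), and Vcam1 fell (-1.28 ± 0.07). Hypoxia genes went both ways, 7 lower and 4 higher of 16, the same adjusted over the list alone (median -0.12, camera adjusted p = 0.0717), with Bnip3 at -2.88 ± 0.08 and Vegfa at 1.57 ± 0.04. In all, 8306 of 13058 tested genes passed the threshold, 4190 higher and 4116 lower (2916 higher and 5551 lower with library totals as the scaling), with 438 higher and 858 lower by over 1 on the log2 scale.

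**Figure D2:**
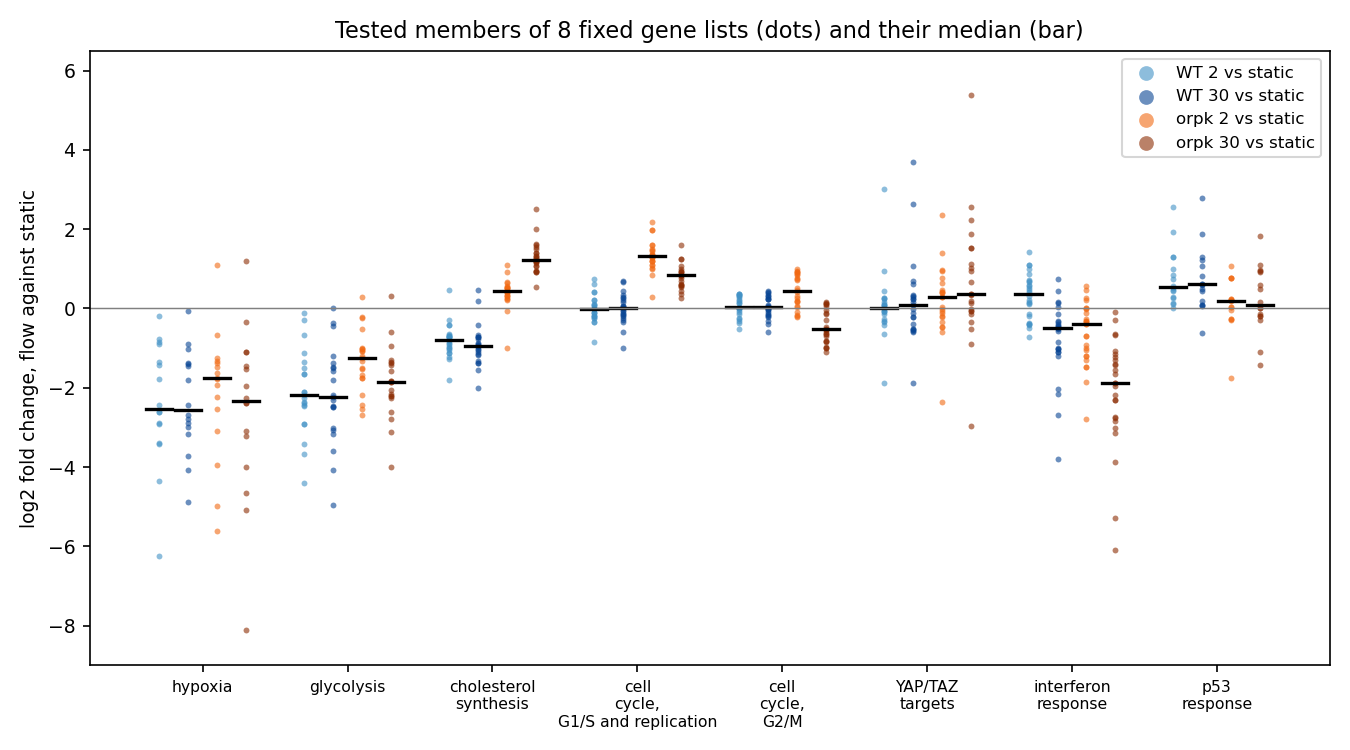
Log2 fold changes of the tested members of 8 fixed gene lists in the 4 comparisons of flow with static cells, 1 dot per gene, with a bar at each list's median. The hypoxia medians lie at -2.52 and -2.56 in WT and at -1.76 and -2.32 in orpk, and the sterol medians at -0.80 and -0.94 in WT and at 0.44 and 1.23 in orpk.

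The genotype comparison asks what differs in cells with the Ift88 mutation, and in static culture the difference exceeded every flow effect by count. Type I collagen and fibroblast genes were high in orpk and keratin genes high in WT. Col1a2 (chromosome 6, 4504814 to 4541544) stood at 19314 ± 210.03 against 18.3 ± 2.74 CPM, a log2 difference of 10.05 ± 0.14. Pdgfra, a receptor of fibroblasts, stood at 1775 ± 18.2 against 0.601 ± 0.231 CPM and Acta2 at 659 ± 40.9 against 0.788 ± 0.0533 CPM. Krt18 and Krt8, keratins of simple epithelium, stood at 0.162 ± 0.149 against 151 ± 4.63 CPM and 0.332 ± 0.176 against 149 ± 3.61 CPM. All 10 tested fibroblast markers were higher in orpk (median 8.95, camera adjusted p = 6.63e-13). Of 37 matrix genes 30 were higher and 6 lower (median 5.07, or 4.10 with genes at 0 reads set to their bound, camera adjusted p = 1.99e-28). Of 9 epithelial and mesothelial markers 7 were lower in orpk and 2 higher (median -4.30, camera adjusted p = 0.0131; adjusted p = 0.0533 with an estimated correlation). Replication genes were lower in 23 of 24 with 0 higher (median -1.45, camera adjusted p = 3.12e-11; adjusted p = 0.0893 with an estimated correlation). Sterol synthesis genes were lower in orpk in 19 of 24 and higher in 3 (median -0.996, camera adjusted p = 1.67e-07). Smooth muscle and pericyte markers were higher in 4 of 5 and lower in 1 (median 6.69, camera adjusted p = 0.0228; adjusted p = 0.07701 with an estimated correlation). All these counts were the same when adjusted over the list alone.

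Several genes were listed at 0 reads in one genotype. The acute phase gene Serpina3n and the guidance gene Slit3 had 0 reads in static WT cells and were at least 4194-fold and 3680.4-fold higher in orpk. The kidney transcription factor gene Pax2 and the tight junction gene Cldn3 had 0 reads in static orpk cells and were at least 1916-fold and 664-fold lower. Of the endothelial identity genes, Pecam1 stood at 0.414 ± 0.179 against 1.27 ± 0.4996 CPM and Cdh5 at 0.598 ± 0.106 CPM in orpk and 0 reads in WT. Of 25 endothelial identity genes 16 had enough reads to test. Of these, 10 were higher in orpk and 5 lower, the same adjusted over the list alone (median 1.45, camera adjusted p = 0.419). Some genes of this list, picked after values were seen, stood higher. Mcam, also in the smooth muscle and pericyte list, stood at 14.3 ± 1.22 CPM in orpk and 149 ± 1.76 in WT. Ets1 stood at 104 ± 3.47 and 150 ± 12.2, and Flt1 at 93.6 ± 1.38 and 40.4 ± 1.04. Cd34, also carried by fibroblasts, stood at 685 ± 11.5 CPM in orpk and 0.286 ± 0.204 in WT. Genes of the Y chromosome were read in both genotypes at different levels, with Ddx3y at 12.6 ± 0.502 against 72.3 ± 2.43 CPM and Kdm5d at 4.98 ± 0.11003 against 44.5 ± 1.57 CPM. The sex chromosome list had 5 of 6 genes lower and 1 higher, the same adjusted over the list alone (median -2.74, camera adjusted p = 0.00266; adjusted p = 0.0893 with an estimated correlation). At 2 and 30 dyn/cm² 5 and 5 of its genes were lower and 0 and 0 higher, also adjusted over the list alone (medians -2.44 and -2.58, camera adjusted p = 0.00323 and 0.00277; adjusted p = 0.15 and 0.0961 with an estimated correlation). Klf2 was 4.35-fold higher in orpk (28.1 ± 2.496 against 6.42 ± 0.954 CPM) and Klf4 2.98-fold higher. The laminar shear list was higher in 13 of 20 and lower in 5, the same adjusted over the list alone (median 1.78, or 1.25 at the bound, camera adjusted p = 0.00534; adjusted p = 0.0893 with an estimated correlation). In all, 11465 of 13058 tested genes passed the threshold, 5795 higher and 5670 lower in orpk (4760 higher and 6765 lower with library totals as the scaling), with 2879 higher and 2381 lower by over 1 on the log2 scale. In this comparison 12 lists passed camera, 6 of them with an estimated correlation.

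Genes of the primary cilium and of pathways it relays were looked at because the mutation lies in a ciliary gene. The design does not separate the mutation from other differences between the WT and orpk cells, such as those in fibroblast and keratin genes. The differences given here therefore cannot be assigned to the mutation or to the cilium. Of 44 ciliary genes, 25 were higher and 16 lower in static orpk cells, the same adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.862). The list passed camera in 0 of the 12 comparisons (2 at an unadjusted p under 0.05, and 10 by fry). The highest and lowest of the named members were Wdr19 (1.79 ± 0.05) and Arl3 (-1.15 ± 0.06). Hedgehog genes, whose signal passes through the cilium, were higher in 10 of 15 and lower in 5, the same adjusted over the list alone (median 2.33, camera adjusted p = 0.159). Gli2 stood at 48.2 ± 1.51 CPM in orpk with 0 reads in WT, and Gas1 at 269 ± 17.5 against 5.11 ± 0.268 CPM. Notch pathway genes were higher in 5 of 14 and lower in 8 (median -0.44, camera adjusted p = 0.419), also when adjusted over the list alone. Genes of the TGF-beta and BMP response were higher in 19 of 28 and lower in 6 (median 0.97, camera adjusted p = 0.00114). Mesenchymal genes were higher in 20 of 22 with 2 lower (median 3.30, camera adjusted p = 9.95e-12). Both counts were the same adjusted over the list alone, and both calls held with an estimated correlation. Glycocalyx genes, of the sugar coat of the cell, were higher in 24 of 41 and lower in 11, the same adjusted over the list alone (median 0.81, camera adjusted p = 6.84e-05), which also held. Of 27 inflammatory adhesion genes 14 were higher and 10 lower (median 1.32, camera adjusted p = 0.0607), and of 17 vascular tone genes 10 and 5 (median 0.65, camera adjusted p = 0.0537). Nuclear genes of oxidative phosphorylation were higher in 5 and lower in 18 of 32 (median -0.15, camera adjusted p = 0.374). Adjusted over the list alone these counts were the same, except 17 lower for oxidative phosphorylation. Macrophage genes were 3 higher and 2 lower of 7 (median -0.26, mean 0.61, camera direction down, adjusted p = 0.862). Ribosomal protein genes were 16 higher and 9 lower of 27 (median 0.26, mean 0.04, camera direction down, adjusted p = 0.983). Both counts were the same adjusted over the list alone.

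At 2 dyn/cm² the genotypes were compared under low shear. Fibroblast markers were higher in orpk in 10 of 10 (median 9.08, camera adjusted p = 1.22e-12). Matrix genes were higher in 31 of 37 with 5 lower (median 3.74, or 3.60 at the bound, camera adjusted p = 3.14e-30). Both counts were the same adjusted over the list alone, and both held with an estimated correlation. Acta2 stood at 1104 ± 93.6 against 0.697 ± 0.227 CPM, Vcam1 at 217 ± 28.04 against 3.08 ± 0.2001 CPM and Krt18 at 0.143 ± 0.0889 against 152 ± 3.32 CPM. Epithelial and mesothelial markers were lower in 6 of 9 and higher in 3, the same adjusted over the list alone (median -1.86, camera adjusted p = 0.033999; adjusted p = 0.0865 with an estimated correlation). That call was lost without orpk replicate 2, which stood apart, with 6 lower and 2 higher (median -2.38, camera adjusted p = 0.109). Smooth muscle and pericyte markers were higher in 4 of 5 and lower in 1, the same adjusted over the list alone (median 5.39, camera adjusted p = 0.00323; adjusted p = 0.02599 with an estimated correlation). With an estimated correlation that call was lost without WT replicate 1 (adjusted p = 0.0605) and without orpk replicate 2 (adjusted p = 0.0883). The keratin gene Krt19 and the mesothelin gene Msln were higher in orpk, at 53.5 ± 5.59 against 17.9 ± 1.25 and 110.5 ± 3 against 40.1 ± 0.541 CPM. Replication genes were higher in 6 of 24 and lower in 14 (median -0.19, camera adjusted p = 0.353), and sterol genes in 17 and 6 of 24 (median 0.37, camera adjusted p = 0.735), the same adjusted over the list alone. Wnt10a, a secreted Wnt ligand, had 0 reads in orpk and was at least 730.1-fold lower, while Itgbl1 had 0 reads in WT and was at least 1105-fold higher. Klf2 no longer differed past the threshold (0.08 ± 0.14, edgeR adjusted p = 0.574), and Klf4 was 5.503-fold higher in orpk. In all, 11432 of 13058 tested genes passed the threshold, 5826 higher and 5606 lower (4677 higher and 6834 lower with library totals as the scaling), with 2801 higher and 2063 lower by over 1 on the log2 scale.

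At 30 dyn/cm² the sterol genes had changed sides, with 22 of 24 higher in orpk and 1 lower, the same adjusted over the list alone (median 1.23, camera adjusted p = 1.02e-06; adjusted p = 0.0269996 with an estimated correlation). G2/M genes were lower in 24 of 24 with 0 higher (median -1.76, camera adjusted p = 1.08e-14; adjusted p = 0.0691 with an estimated correlation), the same adjusted over the list alone. Klf4 was 13.7-fold higher in orpk (257 ± 5.602 against 18.7 ± 0.412 CPM), Klf2 2.397-fold and Edn1 2.36-fold higher. Sulf1, a heparan sulfatase, had 0 reads in WT and was at least 2451-fold higher, and Cds1 had 0 reads in orpk and was at least 683-fold lower. In all, 11350 of 13058 tested genes passed the threshold, 5860 higher and 5490 lower (4470 higher and 7143 lower with library totals as the scaling), with 2931 higher and 2179 lower by over 1 on the log2 scale. Epithelial and mesothelial markers were lower in 6 of 9 and higher in 1, the same adjusted over the list alone (median -2.61, camera adjusted p = 0.008898), a call that held with an estimated correlation, while Msln stood at 165 ± 2.77 against 28.3 ± 1.45 CPM. Fibroblast markers were higher in 10 of 10 (median 8.68, or 7.77 at the bound, camera adjusted p = 1.56e-11), and smooth muscle and pericyte markers in 3 of 5 with 1 lower (median 3.88, camera adjusted p = 0.00585). Both counts were the same adjusted over the list alone, and both calls held with an estimated correlation. Counting genes that passed in all 3 conditions together, 2230 were over 2-fold higher in orpk and 1517 over 2-fold lower.

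**Figure D3:**
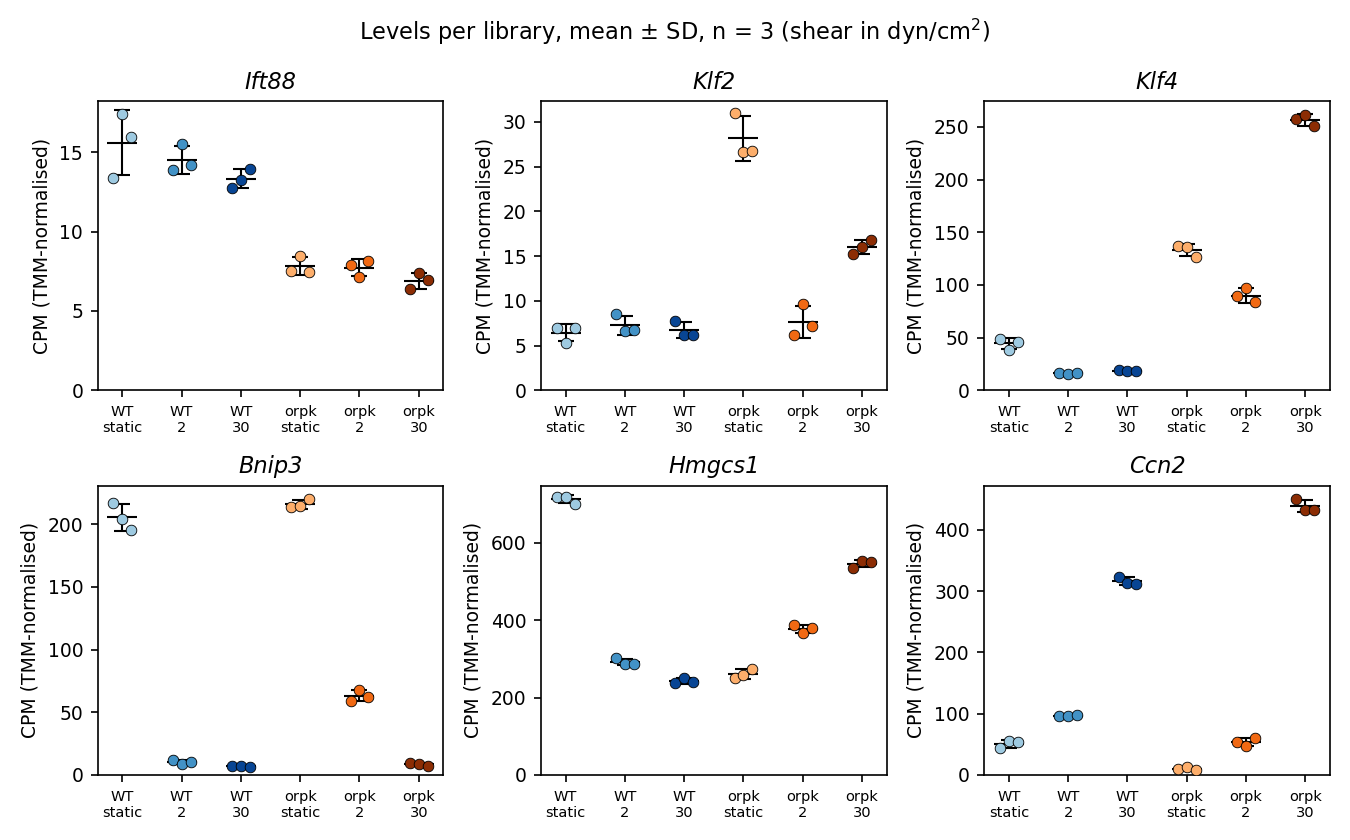
TMM-normalised CPM of 6 genes in each of the 18 libraries (dots) with the group mean and SD (bars, n = 3), by genotype and shear in dyn/cm². Bnip3 falls with flow in both genotypes, from 205 to 6.97 CPM in WT and from 216 to 8.58 CPM in orpk.

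Whether the response to flow itself differed by genotype was tested as an interaction, orpk change minus WT change. At 2 dyn/cm² against static the difference passed for 6864 genes, 3541 higher in orpk and 3323 lower. Replication genes had the higher change in orpk in 24 of 24 and sterol genes in 23 of 24, with 0 and 0 lower and medians of 1.32 and 1.26 (camera adjusted p = 1.09e-67 and 1.69e-61). Targets of p53 had the lower change in 9 of 16, with 0 higher and a median of -0.35 (camera adjusted p = 5.25e-07). These 3 calls held with an estimated correlation, with the same counts adjusted over the list alone. Of genes named by rule with more than 3 reads in each group, Aldoc, a glycolytic aldolase, differed by 4.70 ± 0.39 and Car9 by 4.14 ± 0.24 on the log2 scale. In orpk, Aldoc stood at 0.633 ± 0.177 CPM in static cells and 0.771 ± 0.143 at 2 dyn/cm², against 255 ± 10.2 and 12.1 ± 1.33 in WT. Car9 stood at 14.02 ± 0.628 and 8.45 ± 0.929 in orpk.

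At 30 dyn/cm² against static the difference passed for 7504 genes, 3992 higher and 3512 lower (3275 higher and 4382 lower with library totals as the scaling). All 24 sterol genes had the higher change in orpk (median 2.12, camera adjusted p = 3.27e-140). YAP and TAZ targets had the higher change in 17 of 23 and the lower in 3 (median 0.51, camera adjusted p = 1.73e-06). Targets of p53 had the lower in 8 of 16 and the higher in 4 (median -0.36, camera adjusted p = 3.24e-04). These 3 calls held with an estimated correlation, with the same counts adjusted over the list alone. C1qtnf3, a secreted C1q-domain protein, differed by 5.83 ± 0.92, the skeletal actin gene Acta1 by 4.48 ± 0.51 and the matrix gene Spon2 by -5.79 ± 0.39 on the log2 scale.

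From 2 to 30 dyn/cm² the difference passed for 6073 genes, 3261 higher and 2812 lower (2386 higher and 3756 lower with library totals as the scaling). Sterol genes had the higher change in orpk in 23 of 24, or 24 adjusted over the list alone, with 0 lower (median 0.95, camera adjusted p = 2.08e-48). G2/M genes had the lower change in 24 of 24, also when adjusted over the list alone, with 0 higher (median -0.87, camera adjusted p = 1.49e-36), and both calls held with an estimated correlation. Anxa8 differed by 2.93 ± 0.11, Pi16 by 4.38 ± 0.65 and Txnip by -3.46 ± 0.18 on the log2 scale. In orpk alone Pi16 changed by 4.16 ± 0.13, so most of the SE of its difference comes from WT. Across genotypes, which share no libraries, 1850 were higher in both genotypes, where independent lists would share 1313, and 1839 were lower in both genotypes, where independent lists would share 1231, for 2 dyn/cm² against static. For 30 dyn/cm² against static, 2424 were higher in both genotypes, where independent lists would share 1627, and 2021 were lower in both genotypes, where independent lists would share 1426. At 30 dyn/cm² against static, 797 genes were higher in WT and lower in orpk and 1062 lower in WT and higher in orpk, where independent lists would give 1485 and 1562. With only genes over 1 on the log2 scale counted, these were 44 and 40, where independent lists would give 43.6 and 39.8. From 2 to 30 dyn/cm², 1148 were higher in both genotypes, where independent lists would share 665, and 1035 were lower in both genotypes, where independent lists would share 708. The log2 fold changes of the 13058 genes correlated between genotypes with a Pearson r of 0.2597, 0.286 and 0.261 in these comparisons, across genes, which are not independent replicates.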

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

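The interaction tests were planned, and the counts of other splits and the tests of explanations in this part were chosen after the result was seen. The results here are those whose response to shear differed between WT and orpk by an edgeR quasi-likelihood test of the difference, or by camera for a list. The difference passed for 6864 genes at 2 dyn/cm² against static, 7504 at 30 against static and 6073 at 30 against 2. At 2 against static, the median log2 difference (orpk change minus WT change) was 1.26 for sterol synthesis, 1.32 for replication genes and -0.35 for p53 targets. At 30 against static it was 2.12 for sterol synthesis, 0.51 for YAP and TAZ targets and -0.36 for p53 targets. At 30 against 2 it was 0.95 for sterol synthesis and -0.87 for G2/M genes. Among shear-responsive genes, the log2 difference at 2 against static was -2.04 for Klf2, 0.88 for Klf4, 1.12 for Edn1, 1.85 for Vcam1 and 0.93 for Acta2. At 30 against static it was -0.86 for Klf2, 2.20 for Klf4, 2.01 for Edn1, 1.73 for Vcam1 and 1.66 for Acta2, though WT held under 1 CPM of Acta2. At 30 against 2 it was 1.18 for Klf2, 1.32 for Klf4 and 0.89 for Edn1. Replication genes were lower in orpk in static cells, while at 2 dyn/cm² their list did not pass camera between the genotypes. Klf2 was higher in orpk in static cells and did not differ past the threshold at 2 dyn/cm². For both, flow that brings different static levels to 1 level cannot be told apart from a different response to shear.

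Sterol synthesis genes fell under flow in WT and rose in orpk. Scaling does not account for this, since the smallest of the 3 median differences was 0.86 over 2 other scalings, and neither does 1 library, since it was 0.94 or more without each library in turn. Different static levels brought to 1 level by flow would leave no difference at 30 dyn/cm², where the orpk median stood 1.23 above WT on the log2 scale. The Ift88 mutation may underlie it, and so may any other difference between the WT and orpk cells, which the design does not separate.

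For each interaction, 40 splits that exchanged shear labels within genotypes were drawn with a fixed seed, the real one included. Such a split puts the effect of flow into the residual, so 27, 32 and 36 of the 39 others called 0 genes at 2 against static, 30 against static and 30 against 2, and the splits do not imitate equal responses. They therefore do not decide whether chance explains these counts. At 2 against static 2 of 40 splits called as many genes as the real one, with 6864 genes and a highest other of 8105, from the exchange of all 6 WT labels, which adds the responses of the genotypes in place of subtracting them. At 30 against static and 30 against 2, the exchange of all 6 WT labels and no orpk label was not drawn. There 1 of 40 splits in each called as many genes as the real one, with 7504 and 6073 genes and a highest other of 4940 and 4738.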

How the results depend on the processing

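The alternatives were planned, except that the list tests without WT replicate 1 or orpk replicate 2 at 2 dyn/cm², which stood apart, were chosen after seeing the data. The 12 counts of changed genes stayed within 0.8197 to 1.07 times the reported ones under RLE factors, library totals, no filter, DESeq2, the compared groups alone, the replicate block and each library left out. Library totals as the scaling moved the median of all genes by 0.11 in WT and 0.10 in orpk at 2 against static, by -0.12 in orpk at 30 against 2, and by -0.22, -0.22 and -0.31 between genotypes at static, 2 and 30 dyn/cm² on the log2 scale. There 79, 134 and 404 genotype calls changed sign, and 0 in the other 9 comparisons.

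The number of lists called depended on the test, given here for the 12 comparisons in the order of WT at 2, at 30 and 30 against 2, the same in orpk, genotype at static, 2 and 30, and the interactions in the order of the shear comparisons. With camera as reported it was 6, 5, 11, 13, 12, 14, 12, 9, 17, 10, 9 and 9. With an estimated correlation it was 5, 5, 0, 4, 4, 2, 6, 6, 9, 3, 3 and 2. With fry in a direction it was 20, 20, 18, 27, 25, 25, 26, 27, 28, 26, 22 and 18, and with fry in either direction 28, 29, 27, 29, 28, 28, 29, 29, 29, 29, 28 and 28. With camera under the replicate block it was 8, 6, 8, 13, 10, 13, 10, 8, 11, 12, 8 and 9. Without that WT replicate camera called 6, 10, 9, 8 and 9 lists in WT at 2 against static, WT at 30 against 2, genotype at 2 and the interactions at 2 against static and 30 against 2. Without that orpk replicate it called 13, 13, 8, 12 and 8 in orpk at 2 against static, orpk at 30 against 2 and the same last 3. Fry tests each list for itself and camera against the other genes, and the cause of the lower count under the block at 30 dyn/cm² between genotypes was not tested.

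With only genes over 1 on the log2 scale counted, which leaves fewer genes, the genotypes shared 40 higher and 144 lower at 2 against static, 115 and 294 at 30 against static, and 52 and 61 at 30 against 2. Independent lists would share 10.4 and 22.3, 23.2 and 74.9, and 4.46 and 11.9. Opposite calls, higher and lower in WT, were 18 and 10 at 2 against static and 4 and 6 at 30 against 2, where independent lists would give 13.5 and 17.2, and 8.74 and 6.07. On library totals the Ift88 level was 7.005 CPM in static orpk, 6.14 in orpk at 30, 16.3 in WT at 2 and 14.8 in WT at 30 dyn/cm², as the scaling factors differ between genotypes. Of 120 results for named genes, 116 kept direction and side of the threshold under each alternative run, and 0 reversed. The exceptions were Ift88 in WT at 30 against static, lost at -0.14 with library totals and at -0.22 to -0.15 without 1 of 4 libraries, and Nos3 in the same comparison and Vcam1 in orpk at 2 against static, each past the threshold under some. The fourth was Vcam1 in WT at 30 against 2, lost at -1.19 without replicate 1 at 2 dyn/cm². Depth limits the genes at few reads, for which only bounds or intervals are given.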

Other observations

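The gene list tests and the 9 comparisons in this part were planned, and the kidney list, the tests of explanations and the counts of other splits were chosen after the result was seen. Levels of some kidney genes differed between the genotypes, while 10 of the 19 listed were under 1 CPM in every library. The kidney transcription factor genes Pax2 and Pax8 stood at 132 and 369 CPM in static WT cells and at 40.03 and 149.7 CPM at 30 dyn/cm². In static orpk cells Pax8 stood at 0.573 CPM, and Pax2 had 0 reads. The kidney cadherin gene Cdh16 stood at 666 CPM in static WT and 0.488 in static orpk, Emx2 at 47.6 and 9.55, and Lrp2 at 198 and 5.73. The kidney transporter gene Slc12a1 went the other way, with 0.0642 CPM in static WT and 2.48 in static orpk. The endothelial cadherin gene Cdh5 had 0 reads in the 9 WT libraries and at most 1.12 CPM in an orpk group.

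In static cells 10 of 10 fibroblast markers were higher in orpk, and of 9 epithelial and mesothelial markers 7 were lower and 2 higher (camera adjusted p = 0.0131, median -4.30; adjusted p = 0.0533 with an estimated correlation). If orpk cultures held the WT cell type at 1% or more, its abundant transcripts would be there, but 64 of 5073 genes of at least 50 CPM in static WT were under 1% of that level in orpk. The converse held for 212 of 5147 genes. These counts argue against either cell type at a share of 1% or more in the other culture. Smaller shares were not tested. Of 19 genes in a kidney list, 8 were at 10 CPM or more in each WT library and 0 in each orpk library. Another 10 were under 1 CPM in every library, Cdh1, Umod, Aqp2 and Hnf4a among them, and 1 was also in an earlier list. Kidney epithelium may be a source of the WT cells, but a list written after values were seen does not test this. Such a source cannot be told apart from another epithelium, or from an effect of the genotype. The labels name the cells aortic endothelial, and no sort is described.

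Hypoxia and glycolysis genes were lower under flow in both genotypes, and scaling is argued against, since the list median closest to 0 over 2 other scalings was -1.13. Still medium over static cells, which may run short of oxygen, predicts a step from static to 2 dyn/cm² and little beyond it. In WT the median of 35 genes moved by -2.18 and then by -0.06, a ratio of 0.0268, but from 2 to 30 dyn/cm² 12 of the genes fell further and 4 rose. In orpk it moved by -1.49 and then by -0.39, a ratio of 0.265, with 23 genes lower and 7 higher. As members went both ways, still medium cannot be told apart from a response to the shear itself in either genotype.

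For the 9 comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. In each, 1 of 10, the real one, reached the real count. Exchanged labels put the effect of shear or genotype into the residual, so the 9 others called 0 genes in each. The splits therefore do not decide whether chance explains the counts. The real counts were 8214, 8731, 4316, 8090, 9123, 8306, 11465, 11432 and 11350 genes, for WT at 2, at 30 and 30 against 2, the same in orpk, and genotype at static, 2 and 30 dyn/cm², and the highest other was 0 in each.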
